A study of Mus musculus with 15 samples.

How the data were processed

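RNA was sequenced from 15 cultures of BV-2, a mouse microglial cell line, in 5 genotypes with 3 libraries each: wild type (WT), Abcd1 KO, Abcd2 KO, the double knockout of Abcd1 and Abcd2 (DKO) and Acox1 KO. The mutant lines were made with CRISPR/Cas9, per the labels. All cultures were treated with the same vehicle, α-cyclodextrin at 0.5 mM with ethanol at 0.01%, and stranded poly(A) libraries (TruSeq Stranded mRNA) were made from 1000 ng of total RNA, per the labels' protocols. The labels give 3 independent batches of cells per genotype and name no separate clones within one.

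The deposited table holds raw read counts for 53379 Ensembl gene identifiers in 15 columns, all of them used, with no column left out and 0 rows that name no gene. Per the submitters' processing notes the tools were cutadapt 1.10, Bowtie2 2.2.8, STAR 2.5.3a and HTSeq 0.6.1p1 with genome build mm10. The role and order of these tools, the annotation release and the strand setting of the counting are not given in the sources used here. Symbols and positions on GRCm38 came from GENCODE mouse release 21 and were found for 53274 identifiers. Members of gene families with similar sequences (Chil3 and Chil4, Rnase2a and Ang2, the H2 genes) can share reads, and how the counting treated such reads is not known.

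Counts were analysed in R 4.3.3 with edgeR 4.0.16. The default low-count filter (filterByExpr) left 14632 genes, counts were scaled by TMM (factors 0.897 to 1.05), and 1 quasi-likelihood model with genotype as its only term was fitted to all 15 libraries with robust dispersions. Each mutant was compared with WT, the DKO with each other mutant, and the interaction was DKO minus Abcd1 KO minus Abcd2 KO plus WT. P values were adjusted by Benjamini and Hochberg over the 14632 genes of a contrast, and a gene was called at an adjusted p under 0.05. Levels are CPM (counts scaled by TMM library sizes, edgeR's cpm), given as mean ± SD of 3 libraries, and log2 fold changes carry the standard error (SE) of the fit. The contrast of Abcd2 KO with Acox1 KO, those of Abcd1 KO with Abcd2 KO and with Acox1 KO, the counts of silent genes, the median of nearest neighbours and the correlation among genes with unshifted neighbours were added after the data were seen.

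Totals ran from 21154160 to 43326202 counts per library, so that a count of 0 in a library allowed up to 0.0692 to 0.142 CPM (3 counts). Against a group with 0 counts in its 3 libraries, a fold is written as "at least", computed with 3 counts over the group. With 1 to 3 counts in a group the ratio of CPM is given with its exact 95% counting interval, and the fitted log2 value of such a gene depends on the prior count. Intervals and floors cover counting error only, since PCR reads are not independent molecules.

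Fixed before the data were examined were the comparisons, tests, threshold, alternatives, 35 gene lists and the rule for named genes. The rule took the 3 edited genes in every contrast, and the 10 called genes with the largest rise and the 10 with the largest fall in each mutant against WT (5 and 5 elsewhere). These needed at least 5 CPM in the higher group, no overlap between the libraries of the compared groups (which chance gives for 10% of genes with 3 against 3) and a symbol that is not a clone or predicted name. It also took up to 4 called members per list with the largest change, and the 10 and 10 genes with the largest smallest change over the 4 mutants. Genes from the ranking by size are few and extreme by construction.

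The 35 lists covered peroxisome biogenesis; peroxisomal and mitochondrial fatty acid oxidation; ether lipid synthesis; fatty acid synthesis, elongation and desaturation; cholesterol synthesis and uptake, cholesterol efflux and LXR targets, lipid droplets and PPAR targets. They also covered disease-associated and homeostatic microglia, inflammatory cytokines and NF-kB targets, alternative macrophage activation, type I interferon response, MHC class I and class II, phagocytic and complement receptors and the lysosome. The rest were antioxidant genes, unfolded protein and integrated stress response, glycolysis and hypoxia, oxidative phosphorylation, cell cycle, p53 targets, extracellular matrix, immediate early genes, heat shock, and markers of 8 other cell types. Lists with at least 3 tested genes (32 of 35) were tested with camera (limma 3.58.1), which compares a list with all other genes, at a preset correlation of 0.01, adjusted over the 32 lists of a contrast. Camera with an estimated correlation and fry were alternatives. Fry's p asks whether a list's genes moved on balance 1 way and its mixed p whether they changed in either direction, and neither compares the list with other genes.

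Expectations for shared changes came from 20 simulations, and from the product of the list sizes divided by the number of genes. The simulations redrew all 15 libraries, WT included, from the WT mean and the dispersion of each gene. The 4 unchanged mutant groups were then compared with the same redrawn WT group. WT has only 3 libraries, so the controls could not be split into separate sets of at least 2. Library numbers were examined as pairs after removing genotype means. For 14 of 15 libraries the mean correlation with libraries of the other genotypes was highest for their own number. Same-number correlations ran from -0.01 to 0.525, and every pair exceeded 0.1 in 6 of 7 contrasts (not in Abcd2 KO against WT). A fit with the replicate number as a block was run. In those 6 contrasts its value stands beside a result where it changed a call or moved a count by more than 1.5 times, and for Abcd2 KO against WT it stands only with the alternatives.

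Other alternatives were RLE, upper-quartile and total-count scaling, other low-count filters, DESeq2 1.42.0, limma-voom, fits on the libraries of 1 contrast, no robust dispersion, stricter thresholds, prior counts, and leaving out each library in turn. A fit on replicates 2 and 3 of every genotype was added after the data were seen. The procedure was tested on counts simulated for DKO against WT (13919 genes, 200 of them changed). The edgeR test called 41.8% of 1.5-fold, 79.1% of 2-fold and 95.5% of 4-fold changes, and 0.0618% of unchanged genes. A shift of -0.3 given to chromosome 8 in the same simulation came back as a median of -0.29, with 0 other chromosomes called. Simulated genes varied independently and few outside chromosome 8 changed, whereas 50.1% to 56.4% of genes were called in each mutant against WT. The simulated rates were not tested at that share of changed genes, or for genes that vary together. Tables were joined in R (version 1.17.8 of data.table) and figures drawn with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.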

Results

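Poly(A) RNA was counted per gene in 15 libraries of BV-2 cells, an immortalised line of mouse microglia (the resident macrophages of the brain), with 3 libraries in each of 5 genotypes. WT cells were compared with lines edited in Abcd1, in Abcd2, in both (DKO) and in Acox1. Abcd1 and Abcd2 encode transporters that carry very long-chain fatty acids into peroxisomes, and Acox1 encodes the first enzyme of straight-chain fatty acid oxidation there. Total counts per library ran from 21154160 to 39454976 in WT and from 34031082 to 43326202 in Abcd1 KO. They ran from 24774282 to 31021464 in Abcd2 KO, 28168114 to 38871824 in DKO and 31803749 to 39444949 in Acox1 KO. Mitochondrial genes took 0.483% to 1.51% of counts, ribosomal protein genes 1.15% to 1.72%, and the 10 most counted genes 3.34% to 10.1%. The mean share of ribosomal protein genes was 1.57% in WT (SD 0.143) and 1.34% to 1.38% in the mutants. That of mitochondrial genes was 0.798% in WT (SD 0.275) and 0.870% to 1.16% in the mutants, and WT and mutant libraries overlapped in both. Replicates of a genotype correlated at 0.982 to 0.995 (Pearson's r of log2 CPM across genes, which are not independent replicates). The labels name no separate clones within a genotype, so that genotype and line could not be separated, and p values measure the spread between batches of cells of a line.

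The edited genes were read first in every group. Abcd1 (ENSMUSG00000031378, GRCm38 chromosome X, 73716597 to 73738534) stood at 58.4 ± 9.28 CPM in WT, 55.4 ± 2.88 in Abcd1 KO, 55.4 ± 2.40 in DKO, 104 ± 3.94 in Abcd2 KO and 110 ± 6.03 in Acox1 KO (SD, n = 3 each). It was higher than in WT in Abcd2 KO (log2 fold change 0.83, SE 0.102, adjusted p = 1.1e-05) and in Acox1 KO (0.91, adjusted p = 4.8e-06), changes being given on the log2 scale throughout. It was not called in Abcd1 KO (-0.08, SE 0.101, adjusted p = 0.561) or DKO (-0.07, adjusted p = 0.568). Without WT replicate 2 the value in Abcd1 KO was -0.22 and was called (adjusted p = 0.0482). Abcd2 (ENSMUSG00000055782, chromosome 15, 91145871 to 91191799) fell to 19.2 ± 6.76 CPM in DKO from 276 ± 109 in WT (-3.85, SE 0.522, adjusted p = 2.7e-05). Its levels in Abcd2 KO (168 ± 82.9 CPM, -0.72, adjusted p = 0.204), Abcd1 KO (130 ± 84.8 CPM, -1.09, adjusted p = 0.0629) and Acox1 KO (202 ± 65.9 CPM, -0.45, adjusted p = 0.443) were not called against WT. For Abcd1 KO the call appeared without WT replicate 2 (adjusted p = 0.0321), without Abcd1 KO replicate 1 (0.00892) and with the replicate block (0.00144). Acox1 (ENSMUSG00000020777, chromosome 11, 116171888 to 116199045) was higher than in WT (100 ± 28.3 CPM) in all 4 mutants. It stood at 187 ± 25.1 CPM in Abcd1 KO (0.90, SE 0.188, adjusted p = 0.00103) and 248 ± 37.1 in Abcd2 KO (1.31, adjusted p = 5.1e-05). In DKO it stood at 164 ± 8.63 CPM (0.71, adjusted p = 0.00562) and in Acox1 KO itself at 159 ± 27.8 (0.66, adjusted p = 0.00882). A gene-level count need not fall when Cas9 leaves a small insertion or deletion, so these levels do not test the genotype labels.

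**Figure D1:**
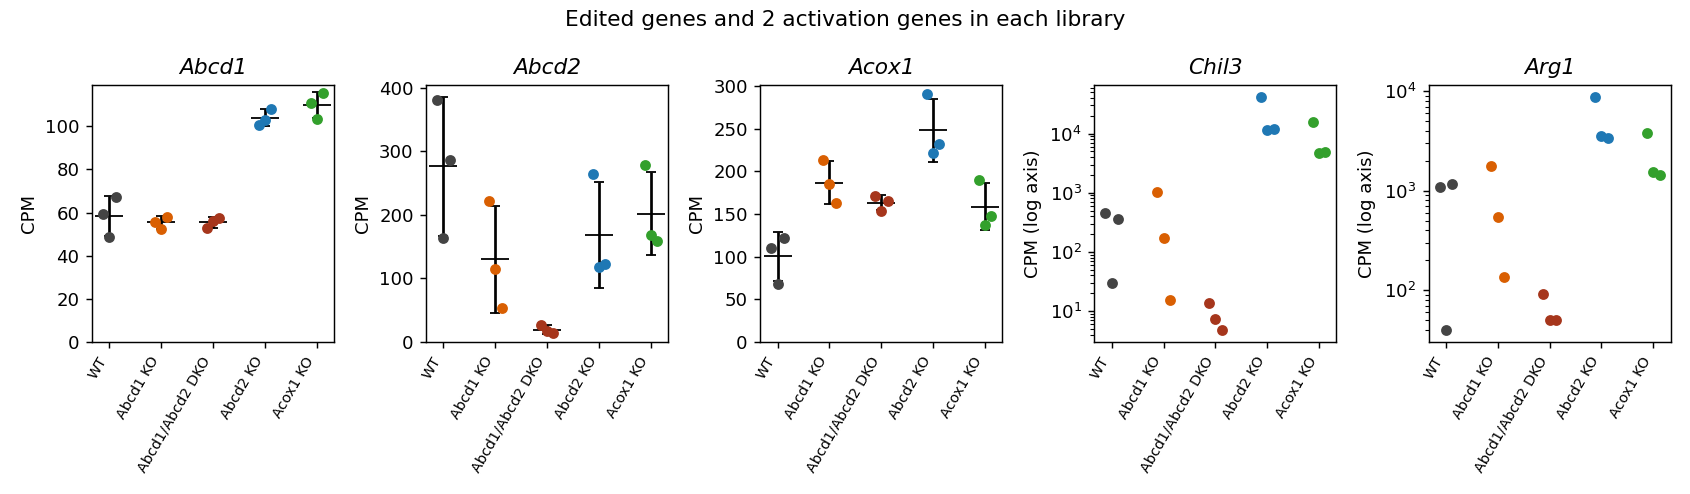
Levels of Abcd1, Abcd2 and Acox1 (CPM, axis from 0, points are libraries with mean ± SD of 3) and of Chil3 and Arg1 (CPM on a log axis, points only) in the 5 genotypes. Acox1 lay higher in the Acox1 KO libraries (mean 159 CPM) than in WT (mean 100 CPM), Abcd2 was lowest in DKO (mean 19.2 CPM), and Chil3 spanned means from 8.54 CPM in DKO to 21940 CPM in Abcd2 KO.

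Libraries of WT, Abcd1 KO and DKO grouped by genotype, those of Abcd2 KO and Acox1 KO lay together, and the mutant genotypes lay in pairs. Abcd1 KO and DKO were 0.42 apart (root mean square of log2 differences across genes between group means) and Abcd2 KO and Acox1 KO 0.48 apart. The remaining distances among mutants were 0.88 to 1.02, and those from WT to a mutant 1.30 to 1.35. The first principal component held 47.3% and the second 31.4% of the variance. On both, the scores of Abcd2 KO (32.1 to 41.6 and 49.5 to 57.2) and Acox1 KO (34.4 to 36.4 and 48.0 to 55.4) overlapped. Replicate 1 was the highest in each of these genotypes.

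**Figure D2:**
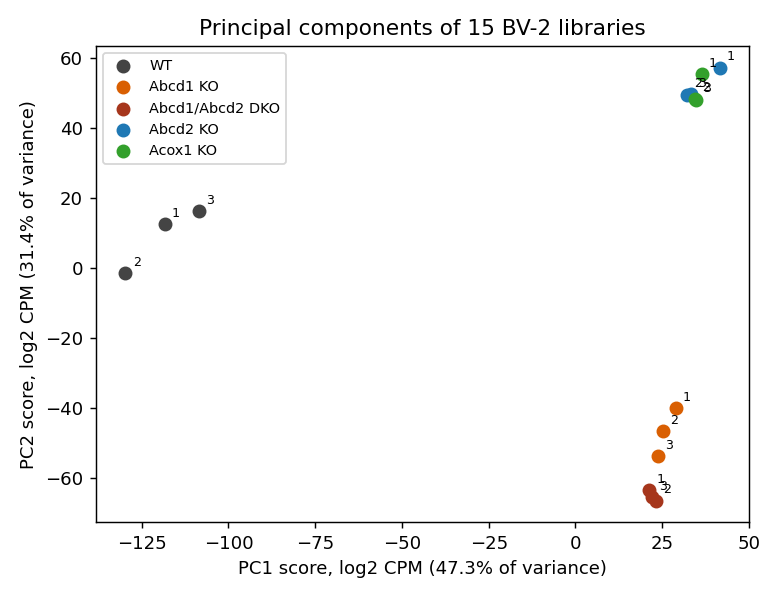
First (47.3% of variance) and second (31.4%) principal components of log2 CPM for the 15 libraries, coloured by genotype and numbered by replicate. WT stands apart from the mutants on one axis, and Abcd1 KO with DKO stands apart from Abcd2 KO with Acox1 KO on the other.

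Abcd1 KO was compared with WT to ask which genes differ in cells edited in the transporter gene mutated in X-linked adrenoleukodystrophy. Fads2 (delta-6 desaturase, ENSMUSG00000024665, chromosome 19, 10062765 to 10101746) fell from 189 ± 12.4 to 0.0536 ± 0.00668 CPM (-11.70, SE 0.269, adjusted p = 1.0e-12). Scd1 (stearoyl-CoA desaturase, ENSMUSG00000037071, chromosome 19, 44394455 to 44407879) fell from 294 ± 37.1 to 0.126 ± 0.0642 CPM (-11.17, SE 0.252). Qsox1, a secreted sulfhydryl oxidase, was at least 1702-fold lower (46.1 ± 5.29 CPM in WT, 0 counts in the mutant). Rnd3, a small Rho-family GTPase, was at least 942-fold lower. Tuba4a, an alpha tubulin, was lower by a ratio of 6931 (95% counting interval 2371 to 33610). Tspan7, a tetraspanin, rose from 2.10 ± 0.623 to 118 ± 3.85 CPM (5.83, SE 0.305, adjusted p = 3.0e-09). Chit1, a chitinase of activated macrophages, rose by 6.16 (SE 0.364), Cfh, the complement regulator factor H, by 5.24 (SE 0.301), and Grik4, a kainate receptor subunit, by 5.04 (SE 0.276). Rgs18, a regulator of G-protein signalling, was higher by a ratio of 803 (interval 144 to 31730, 1 count in WT). At an adjusted p under 0.05, 3979 genes were higher and 3702 lower. These 7681 genes were 52.5% of the 14632 tested, and 3281 of them differed by at least 2-fold.

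Among the gene lists, disease-associated microglia genes rose in Abcd1 KO (27 of 32 higher and 0 lower, 28 and 0 adjusted over the list alone, median 1.07, camera adjusted p = 9.5e-07, adjusted p = 0.336 with an estimated correlation). They included Spp1, which encodes osteopontin (3238 ± 464 to 11870 ± 1142 CPM, 1.87, SE 0.189), and Lyz2, a lysozyme of myeloid cells (2.35, SE 0.278). Lysosome genes rose (30 of 36 higher and 1 lower, 31 and 1 adjusted over the list alone, median 0.62, adjusted p = 3.8e-05, adjusted p = 0.940 with an estimated correlation). Atp6v0d2, a subunit of the proton pump (2.96, SE 0.414), and the protease Ctsb (1.25, SE 0.119) rose. Of 17 p53 targets 13 were higher and 1 lower, the same counts adjusted over the list alone (median 0.89, adjusted p = 0.000928, adjusted p = 0.336 with an estimated correlation). Trp53inp1, a p53-induced protein, rose most (33.4 ± 0.724 to 202 ± 14.3 CPM, 2.59, SE 0.113). Interferon response genes rose (19 of 25 higher and 2 lower, 19 and 2 adjusted over the list alone, median 1.04, adjusted p = 0.00811, adjusted p = 0.940 with an estimated correlation). Mx1, an antiviral GTPase, rose by 3.55 (SE 0.496). Cell cycle genes fell (0 of 26 higher and 17 lower, 0 and 17 adjusted over the list alone, median -0.57, adjusted p = 0.0121, adjusted p = 0.940 with an estimated correlation). Ccnd1, which encodes cyclin D1, fell by 1.79 (SE 0.109). Inflammatory cytokine genes fell (2 of 22 higher and 11 lower, 2 and 11 adjusted over the list alone, median -0.97, adjusted p = 0.0172, adjusted p = 0.713 with an estimated correlation). Tnf fell strongly (82.3 ± 18 to 7.80 ± 0.872 CPM, -3.40, SE 0.228). The list of fatty acid synthesis, elongation and desaturation fell by the test (5 of 19 higher and 8 lower, 5 and 8 adjusted over the list alone, adjusted p = 0.0187, adjusted p = 0.336 with an estimated correlation). Its median was -0.11 and its mean, which Fads2 and Scd1 weighed on, -1.02. The elongase genes Elovl7 (2.64, SE 0.166) and Elovl4 (1.81, SE 0.216), which extend fatty acid chains, rose within it.

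Abcd2 KO was compared with WT to ask which genes differ in cells edited in the closest relative of Abcd1. The chitinase-like genes Chil3 and Chil4, secreted by alternatively activated macrophages, rose. Chil3 went from 278 ± 220 to 21940 ± 17530 CPM (6.30, SE 1.36, adjusted p = 0.00128) and Chil4 from 0.363 ± 0.319 to 41.2 ± 30.2 CPM (6.96, SE 0.848). Rnase2a (4.88, SE 0.810) and Ang2 (5.22, SE 0.639), secreted ribonucleases, rose, as did the eosinophil chemoattractant Ccl24 (8.03 ± 3.96 to 122 ± 58.4 CPM, 3.94, SE 0.571). Replicate 1 held the highest Chil3 of the 3 libraries in every genotype, at 3.57 times the mean of the others in Abcd2 KO and 2.33 times in WT. Plac8, a small cysteine-rich protein, was at least 1075-fold lower (40.2 ± 4.95 CPM in WT). Sdr39u1, a predicted dehydrogenase, was at least 989-fold lower and Lamtor4, a subunit of the lysosomal Ragulator complex, at least 575-fold lower. Fads2 was lower by a ratio of 5122 (interval 1752 to 24840), and Scd1 fell by 10.11 (SE 0.240). Called genes numbered 8259 (56.4%), of which 4189 were higher, 4070 lower and 3452 changed by at least 2-fold.

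In Abcd2 KO lysosome genes rose (33 of 36 higher and 1 lower, 33 and 1 adjusted over the list alone, median 0.93, adjusted p = 9.9e-09, adjusted p = 0.549 with an estimated correlation). Gba (1.30, SE 0.131) and Gla (1.29, SE 0.127), which degrade glycolipids, rose. Disease-associated microglia genes rose (24 of 32 higher and 3 lower, 25 and 3 adjusted over the list alone, median 0.97, adjusted p = 6.7e-05, adjusted p = 0.549 with an estimated correlation). The receptor Clec7a (2.07, SE 0.411) and the growth factor Igf1 (218 ± 69.6 to 650 ± 59.4 CPM, 1.57, SE 0.231) rose. MHC class I genes rose (14 of 15 higher and 1 lower, 14 and 1 adjusted over the list alone, median 0.89, adjusted p = 0.00164, adjusted p = 0.549 with an estimated correlation). H2-D1 rose by 1.28 (SE 0.115), and 12 of the 15 lie on chromosome 17. Interferon response genes rose (16 of 25 higher and 3 lower, 16 and 3 adjusted over the list alone, median 1.30, adjusted p = 0.0112, adjusted p = 0.549 with an estimated correlation). Mx1 rose by 3.41 (SE 0.501). Mitochondrial fatty acid oxidation genes rose (14 of 18 higher and 2 lower, 14 and 2 adjusted over the list alone, median 0.50, adjusted p = 0.0252, adjusted p = 0.549 with an estimated correlation). Hadh (1.43, SE 0.138) and Cpt1a, the entry step of the pathway (1.09, SE 0.176), rose. Oxidative phosphorylation genes were higher in 15 of 21 and lower in 1, with the same counts adjusted over the list alone (median 0.30, adjusted p = 0.0208, adjusted p = 0.549 with an estimated correlation). That call was lost without WT replicate 1 (adjusted p = 0.0569) and with total-count scaling (0.0586). Cell cycle genes fell (1 of 26 higher and 19 lower, 1 and 20 adjusted over the list alone, median -0.82, adjusted p = 0.00164, adjusted p = 0.591 with an estimated correlation). Rrm2, a subunit of ribonucleotide reductase, fell by 1.53 (SE 0.257). Fatty acid synthesis genes fell by the test (6 of 19 higher and 7 lower, 7 and 7 adjusted over the list alone, median -0.08, mean -1.20, adjusted p = 0.00460, adjusted p = 0.273 with an estimated correlation). Fads2, Scd1 and the elongase Elovl6 (-2.06, SE 0.213) fell most.

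Several lists stood near the threshold in Abcd2 KO. Of the 11 genes of alternative macrophage activation 8 were higher and 0 lower (median 2.15, adjusted p = 0.0584), including the lectins Mgl2 (3.41, SE 0.599) and Mrc1 (2.37, SE 0.331). That list was called without WT replicate 1 (adjusted p = 0.0493), WT replicate 3 (0.0493), Abcd2 KO replicate 2 (0.0341) or Abcd2 KO replicate 3 (0.0419). Markers of border macrophages, a list that also holds Mrc1, stood beside it (3 of 5 higher and 0 lower, 4 and 0 adjusted over the list alone, median 2.36, adjusted p = 0.116). Arg1, the arginase of alternative activation, was at 5274 ± 3112 CPM against 768 ± 631 in WT (2.78, SE 0.990, adjusted p = 0.0269) and lost its call without Abcd2 KO replicate 1 (adjusted p = 0.149). Inflammatory cytokine genes were higher in 5 and lower in 10 of 22 (median -0.35, adjusted p = 0.0584), with a call without WT replicate 3 (0.00857). Il23a, a cytokine subunit, fell by 4.51 (SE 0.435). Cholesterol efflux genes (7 of 10 higher, adjusted p = 0.0676) were called without WT replicate 3 (0.0391) or Abcd2 KO replicate 2 (0.0345). Phagocytic receptor genes (15 of 25 higher and 3 lower, adjusted p = 0.116) were called without Abcd2 KO replicate 2 (0.0371).

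DKO was compared with WT to ask which genes differ when both transporter genes are edited. Rxfp1, the relaxin receptor, rose from 0.130 ± 0.0299 to 14.9 ± 4.24 CPM (6.83, SE 0.372, adjusted p = 4.3e-09). Il7r, the interleukin 7 receptor, rose by 5.67 (SE 0.348) and Tspan7 by 6.31 (SE 0.309). Hgf, hepatocyte growth factor, was higher by a ratio of 260 (interval 71.6 to 2151). The complement genes C1qb (113 ± 40.2 to 6.91 ± 0.571 CPM, -4.03, SE 0.237), C1qa (-3.96, SE 0.416) and C1qc (-3.59, SE 0.288), whose products start the classical pathway, fell, as did C3 (-2.66, SE 0.414). Chil3 fell to 8.54 ± 4.6 CPM (-5.02, SE 1.31, adjusted p = 0.00497) and Arg1 to 63.6 ± 24.2 CPM (-3.59, SE 1.03, adjusted p = 0.00907), with replicate 1 at 2.28 and 1.85 times the mean of the others. For Arg1 the groups overlapped: WT replicate 2 (39.7 CPM) lay below all 3 DKO libraries (91.6, 49.6 and 49.6 CPM). Its call was lost with limma-voom (adjusted p = 0.0769) and on replicates 2 and 3 (0.0613). Stk26, a stress-linked kinase, was at least 1264-fold lower and Tmeff1, a transmembrane protein, at least 1171-fold lower. Dhcr24, the last enzyme of a cholesterol synthesis branch, was lower by a ratio of 7682 (interval 2126 to 63440), and Scd1 fell to 0.0478 ± 0.0243 CPM (-12.40, SE 0.279, adjusted p = 1.3e-12). In total 7598 genes (51.9%) were called, 3852 higher and 3746 lower, with 3281 at 2-fold or more.

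In DKO disease-associated microglia genes rose (23 of 32 higher and 2 lower, 24 and 2 adjusted over the list alone, median 1.03, adjusted p = 1.3e-05, adjusted p = 0.505 with an estimated correlation). Spp1 rose by 1.96 (SE 0.190), while Axl, a receptor for dying cells, fell by 2.59 (SE 0.656). Lysosome genes rose (24 of 36 higher and 2 lower, 24 and 2 adjusted over the list alone, median 0.50, adjusted p = 0.00118, adjusted p = 0.888 with an estimated correlation). The protease Ctsk rose by 1.44 (SE 0.170), while Ctsc, another protease, fell by 1.48 (SE 0.135). Targets of p53 rose (13 of 17 higher and 1 lower, 13 and 1 adjusted over the list alone, median 0.91, adjusted p = 0.00169, adjusted p = 0.448 with an estimated correlation). Eda2r, a receptor of the tumour necrosis factor receptor family, rose (10.4 ± 7.10 to 50.5 ± 2.77 CPM, 2.25, SE 0.324). Inflammatory cytokine genes fell (2 of 22 higher and 12 lower, 2 and 12 adjusted over the list alone, median -1.12, adjusted p = 0.0298, adjusted p = 0.724 with an estimated correlation). The chemokine Cxcl3 was at least 130-fold lower, and the list lost its call without WT replicate 1 (adjusted p = 0.0703). Fatty acid synthesis genes fell by the test (5 of 19 higher and 6 lower, 5 and 6 adjusted over the list alone, median -0.14, mean -1.12, adjusted p = 0.0352, adjusted p = 0.448 with an estimated correlation). That list lost its call without DKO replicate 2 (adjusted p = 0.0603) and with the replicate block (0.0911). Cell cycle genes (0 of 26 higher and 14 lower, adjusted p = 0.0584) were called without WT replicate 3 (0.0370) or DKO replicate 1 (0.0420). Interferon response genes (12 of 25 higher and 3 lower, adjusted p = 0.106) were called without WT replicate 3 (0.0347).

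Acox1 KO was compared with WT to ask which genes differ in cells edited in the first enzyme of the pathway that the transporters feed. Rbp7, a retinol-binding protein, was at 10.6 ± 0.824 CPM against 0 counts in WT, at least 339-fold higher. Chil3 rose to 8532 ± 6357 CPM (4.94, SE 1.28, adjusted p = 0.00509), with replicate 1 at 3.26 times the mean of the others. Lamb1, a laminin chain (4.86 ± 3.64 to 53.7 ± 20.3 CPM, 3.50, SE 0.642), Sema3b, a secreted guidance factor (3.86, SE 0.385), and Ccl24 (3.34, SE 0.558) rose. Dhcr24 was at least 5298-fold lower (0 counts against 150 ± 33.6 CPM). Cbs, the first enzyme of transsulfuration, was at least 1396-fold lower, and Cxcl14, a chemokine, at least 1388-fold lower. Fads2 was lower by a ratio of 9796 (interval 2712 to 80900), and Scd1 fell by 10.05 (SE 0.234, adjusted p = 1.4e-12). Called genes numbered 7330 (50.1%), with 3645 higher, 3685 lower and 3023 changed by at least 2-fold.

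In Acox1 KO lysosome genes rose (30 of 36 higher and 0 lower, 30 and 0 adjusted over the list alone, median 0.88, adjusted p = 1.7e-07, adjusted p = 0.798 with an estimated correlation). Ctsb rose from 1328 ± 179 to 3408 ± 430 CPM (1.36, SE 0.119). Interferon response genes rose (18 of 25 higher and 2 lower, 18 and 3 adjusted over the list alone, median 1.51, adjusted p = 0.000344, adjusted p = 0.798 with an estimated correlation). The antiviral gene Rsad2 rose by 2.80 (SE 0.321). Disease-associated microglia genes rose (20 of 32 higher and 3 lower, 20 and 3 adjusted over the list alone, median 0.79, adjusted p = 0.000366, adjusted p = 0.798 with an estimated correlation). Lgals3, which encodes galectin-3, rose from 612 ± 235 to 1919 ± 247 CPM (1.65, SE 0.220). MHC class I genes rose (12 of 15 higher and 1 lower, 13 and 1 adjusted over the list alone, median 0.80, adjusted p = 0.00824, adjusted p = 0.798 with an estimated correlation). The immunoproteasome subunit Psmb8 rose by 1.25 (SE 0.136). The list of fatty acid synthesis had a median of 0.00 and a mean of -1.25 and fell by the test (4 of 19 higher and 6 lower, 4 and 6 adjusted over the list alone, adjusted p = 0.00673, adjusted p = 0.224 with an estimated correlation). Elovl6 fell by 1.64 (SE 0.209). Oxidative phosphorylation genes were higher in 12 and lower in 0 of 21, 13 and 0 adjusted over the list alone (median 0.31, adjusted p = 0.0419, adjusted p = 0.798 with an estimated correlation). Atp5c1, a subunit of ATP synthase, rose by 0.74 (SE 0.0744). Inflammatory cytokine genes were higher in 3 and lower in 10 of 22, 3 and 11 adjusted over the list alone (median -0.36, adjusted p = 0.0419, adjusted p = 0.798 with an estimated correlation). Il23a fell by 4.04 (SE 0.401). The oxidative phosphorylation call was lost without WT replicate 1 (adjusted p = 0.105), WT replicate 2 (0.0584), Acox1 KO replicate 2 (0.0788) or replicate 3 (0.0569), and with RLE (0.0557) or total-count scaling (0.0912). The cytokine call was lost without WT replicate 1 (0.0920) or Acox1 KO replicate 2 (0.0590), and with RLE (0.0545) or total-count scaling (0.0630). Mitochondrial fatty acid oxidation genes (12 of 18 higher and 2 lower, adjusted p = 0.10) were called without WT replicate 3 (0.0253).

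All 4 mutants shared a large part of their difference from WT. Syne2, a nuclear envelope protein, rose by 2.37, 2.38, 3.50 and 2.92 in Abcd1 KO, Abcd2 KO, DKO and Acox1 KO. Gpr55, a lipid receptor, rose in the same order by 2.53, 2.27, 2.44 and 2.54. Plin2, a lipid droplet coat protein, rose by 1.18, 1.08, 1.60 and 1.05, and Hadh by 1.38, 1.43, 1.33 and 1.24. The peroxisomal genes Nudt7 and Acox3 rose by 0.96 to 1.67 and by 0.88 to 1.34. Fads2, Scd1, Dhcr24, Tuba4a, Rnd3, Plac8 and the monoglyceride lipase Mgll fell in all 4. Chac1, a target of the integrated stress response, fell (-3.02, -2.56, -3.39 and -3.62). Phyh, the peroxisomal enzyme of phytanic acid breakdown, was lower by ratios of 174 (interval 47.7 to 1441), 246 (43.8 to 9756), 303 (54.0 to 12030) and 314 (55.9 to 12440). Genes called the same way in all 4 numbered 4063 (1954 higher and 2109 lower, 27.8% of those tested). Independent lists would share 74.7 higher and 66.4 lower genes. In 20 simulations of unchanged mutants against 1 redrawn WT group 0 genes were shared (highest 0), but such mutants give almost no calls at all. Part of the excess over independence may come from the WT libraries that all 4 comparisons use.

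Fold changes against WT correlated across genes at 0.943 between Abcd1 KO and DKO and at 0.930 between Abcd2 KO and Acox1 KO. There, unchanged mutants simulated against a redrawn WT group that they shared gave 0.515 and 0.498. In the other pairs r was 0.774 (Abcd1 KO with Abcd2 KO), 0.772 (Abcd1 KO with Acox1 KO), 0.703 (Abcd2 KO with DKO) and 0.711 (DKO with Acox1 KO). Simulated values were 0.499, 0.508, 0.499 and 0.509. The covariance exceeded the simulated value by 2.47 and 2.64 in the first 2 pairs and by 2.05, 2.09, 1.91 and 1.98 in the others. Abcd1 KO and DKO shared 3363 higher and 3152 lower genes (independent lists 1047.5 and 948) with 12 opposite. Abcd2 KO and Acox1 KO shared 3164 and 3147 (1043.5 and 1025) with 40 opposite. Opposite calls numbered 287 (Abcd1 KO with Abcd2 KO), 289 (Abcd1 KO with Acox1 KO), 436 (Abcd2 KO with DKO) and 382 (DKO with Acox1 KO). Genes are not independent replicates, so no p is attached to these correlations.

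Lists not called in any mutant against WT, with ranges over the 4, included peroxisome biogenesis (6 to 9 of 16 higher, 0 to 2 lower, adjusted p = 0.148 to 0.526). They also included peroxisomal fatty acid oxidation (7 to 11 of 20 higher, 2 to 4 lower, 0.134 to 0.910), with medians of 0.08 to 0.37 and a mean of -0.40 in Abcd1 KO. Phyh was its lowest member there. Ether lipid synthesis (2 of 7 higher, 0 to 3 lower, 0.876 to 0.967) and cholesterol synthesis (3 to 14 of 23 higher, 3 to 8 lower, 0.254 to 0.893) had no call. Cholesterol efflux (2 to 7 of 10 higher, 0 to 4 lower, 0.0676 to 0.923) and lipid droplet genes (3 to 6 of 14 higher, 4 to 5 lower, 0.552 to 0.805) had none. PPAR targets (5 to 7 of 10 higher, 1 to 3 lower, 0.253 to 0.671) were uncalled. Immune lists without a call were homeostatic microglia (4 to 6 of 16 higher, 4 to 6 lower, 0.571 to 0.906) and alternative activation (1 to 8 of 11 higher, 0 to 7 lower, 0.0584 to 0.873). Genes of MHC class II (3 to 5 of 9 higher, 0 to 3 lower, 0.148 to 0.671) and of phagocytic receptors (4 to 15 of 25 higher, 3 to 9 lower, 0.10 to 0.906) were not called. Among stress and metabolic lists these were antioxidant genes (6 to 9 of 24 higher, 3 to 6 lower, 0.478 to 0.919) and the unfolded protein and integrated stress response (3 to 9 of 24 higher, 3 to 12 lower, 0.189 to 0.520). Glycolysis and hypoxia (2 to 7 of 21 higher, 0 to 6 lower, 0.202 to 0.906) and heat shock genes (2 to 3 of 8 higher, 0 to 2 lower, 0.520 to 0.896) had no call. Extracellular matrix (4 to 8 of 22 higher, 7 to 8 lower, 0.427 to 0.906) and immediate early genes (1 to 2 of 9 higher, 2 to 5 lower, 0.385 to 0.923) were also uncalled. Of the markers of other cell types, those of border macrophages (0 to 3 of 5 higher, 0 to 3 lower, 0.116 to 0.919) and of monocytes and neutrophils (0 of 3 higher, 1 lower, 0.290 to 0.385) were not called. Markers of lymphocytes (0 to 2 of 3 higher, 0 lower, 0.373 to 0.552), astrocytes (2 of 3 higher, 0 lower, 0.189 to 0.362) and oligodendrocytes (0 to 1 of 3 higher, 1 lower, 0.385 to 0.552) were not called. Those of neurons, fibroblasts and endothelium had fewer than 3 tested genes.

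**Figure D3:**
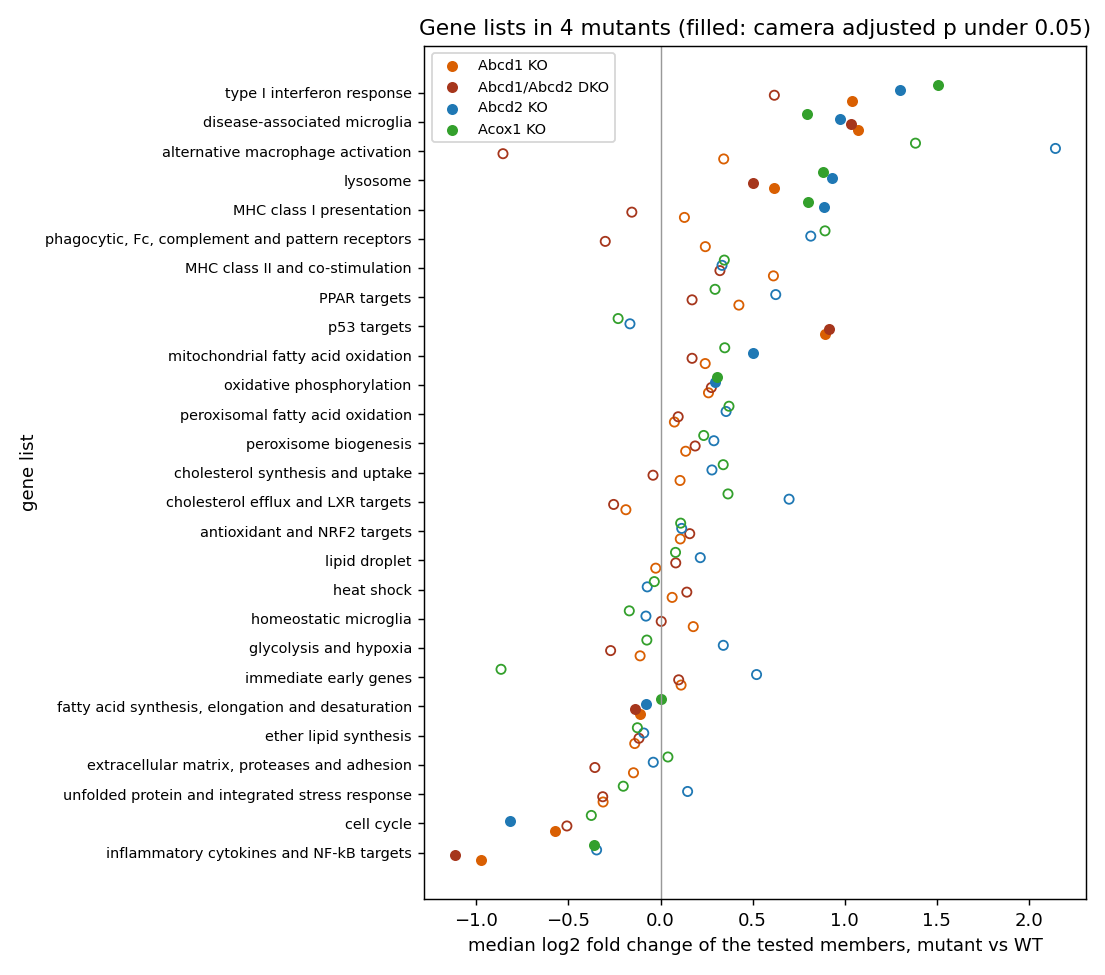
Median log2 fold change against WT of the tested genes of 27 lists in the 4 mutants, with filled points where camera gave an adjusted p under 0.05. Lysosome medians lay between 0.50 and 0.93 and disease-associated microglia medians between 0.79 and 1.07, all filled.

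DKO was compared with Acox1 KO to ask how cells edited in both transporter genes differ from cells edited in the gene of the enzyme they feed. Spink5, a protease inhibitor (26.1 ± 1.15 CPM in DKO, 0 counts in Acox1 KO), was at least 886-fold higher in DKO, and Rgs18 at least 360-fold higher. Chil3 (-9.96, SE 1.60, adjusted p = 0.00025) and Rnase2a (-9.41, SE 1.23) were lower, and Btbd3, a regulator of dendrite shape, was at least 172-fold lower. Targets of p53 were higher in DKO (14 of 17 higher and 0 lower, 14 and 1 adjusted over the list alone, median 1.17, adjusted p = 6.2e-10). Among the lists called in the 6 contrasts tested this alone held with an estimated correlation (adjusted p = 0.0363). Eda2r (0.110 ± 0.0404 CPM in Acox1 KO, 50.5 ± 2.77 in DKO, 8.82, SE 0.528) was higher in DKO within it. So was Mdm2, the ubiquitin ligase of p53 (81.6 ± 2.46 and 228 ± 20.9 CPM, 1.48, SE 0.126). Eda2r stood at 10.4 ± 7.10 CPM in WT, so part of its difference was a lower level in Acox1 KO. Against WT the list's median was 0.91 in DKO (13 of 17 higher and 1 lower). In Acox1 KO it was -0.23, with 3 higher and 7 lower and no call (camera adjusted p = 0.362). MHC class I genes were lower in DKO (0 of 15 higher and 10 lower, 0 and 11 adjusted over the list alone, median -1.05, adjusted p = 4.6e-09, adjusted p = 0.208 with an estimated correlation). H2-K1 was at 110 ± 11.7 against 321 ± 8.95 CPM (-1.54, SE 0.105), and 12 of the 15 lie on chromosome 17. Phagocytic and complement receptor genes were lower (3 of 25 higher and 14 lower, 3 and 14 adjusted over the list alone, median -0.82, adjusted p = 2.6e-05, adjusted p = 0.365 with an estimated correlation). C1qb was at 6.91 ± 0.571 against 290 ± 35.4 CPM (-5.39, SE 0.250). Cholesterol synthesis genes were lower (1 of 23 higher and 15 lower, 1 and 16 adjusted over the list alone, median -0.55, adjusted p = 0.000122, adjusted p = 0.918 with an estimated correlation). The mevalonate pathway gene Mvd was lower by 1.35 on the log2 scale (-1.35, SE 0.187). Genes of alternative activation were lower (1 of 11 higher and 10 lower, 1 and 10 adjusted over the list alone, median -2.24, adjusted p = 0.00565, adjusted p = 0.918 with an estimated correlation). Mrc1 was at 217 ± 39.7 against 1770 ± 224 CPM (-3.03, SE 0.341).

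In the same comparison markers of border macrophages were lower in DKO (0 of 5 higher and 4 lower, 0 and 5 adjusted over the list alone, median -1.79, adjusted p = 0.00649, adjusted p = 0.720 with an estimated correlation). Cbr2, a carbonyl reductase, stood at -3.16 (SE 0.541). These markers move beside the alternative activation genes, and Mrc1 belongs to both lists. Interferon response genes (4 of 25 higher and 10 lower, 4 and 11 adjusted over the list alone, median -0.49, adjusted p = 0.0464, adjusted p = 0.968 with an estimated correlation) lost their call without DKO replicate 1 (0.0612), 2 (0.0547) or 3 (0.0516) or Acox1 KO replicate 1 (0.174). Abcg1 (-1.05, SE 0.213) and Abca1 (-1.03, SE 0.148), both sterol exporters, were lower. Their list, cholesterol efflux (0 of 10 higher and 4 lower, 0 and 4 adjusted over the list alone, median -0.47, adjusted p = 0.0464, adjusted p = 0.918 with an estimated correlation), lost its call without DKO replicate 2 (0.0700) or 3 (0.0516) or Acox1 KO replicate 1 (0.0513). Lysosome genes (3 of 36 higher and 10 lower, adjusted p = 0.0674) were called with the replicate block (0.0470) and without DKO replicate 1 (0.0469) or Acox1 KO replicate 2 (0.0451). Abcd1 was lower in DKO (-0.99, adjusted p = 4.4e-06), as was Abcd2 (-3.39, SE 0.512, adjusted p = 0.00015), while Acox1 was not called (0.04, adjusted p = 0.883). A total of 5084 genes (34.7%) were called, 2660 higher and 2424 lower in DKO.

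DKO was compared with Abcd1 KO to ask what the added edit of Abcd2 goes with. Complement genes fell: C1qb from 89.1 ± 13.6 to 6.91 ± 0.571 CPM (-3.69, SE 0.234, adjusted p = 1.5e-06) and C1qc from 30.7 ± 7.79 to 5.41 ± 1.99 CPM (-2.51, SE 0.280). So did the surface antigen Cd52 (-1.73, SE 0.169), the scavenger receptor Msr1 (-1.40, SE 0.251) and Igf1 (-1.32, SE 0.229). Spink5 rose from 0.0614 ± 0.0581 to 26.1 ± 1.15 CPM (8.64, SE 0.573, adjusted p = 3.8e-05), Rxfp1 by 5.11 (SE 0.313) and Il7r by 4.09 (SE 0.297). Wwtr1, which encodes the transcriptional coactivator TAZ, rose by 4.87 (SE 0.483) and Tenm4, a teneurin, by 4.50 (SE 0.401). Abcd2 fell by 2.75 (SE 0.500, adjusted p = 0.00734, lost without DKO replicate 3, 0.0553). Abcd1 (0.00, adjusted p = 1) and Acox1 (-0.19, adjusted p = 0.780) were not called. Of 476 called genes (3.25%) 169 were higher and 307 lower. The count was 1250 with the replicate block, 1106 with only the 6 libraries of the contrast and 868 with DESeq2. It was 191 without Abcd1 KO replicate 1, 205 without replicate 2, 296 without DKO replicate 1, 201 without replicate 2 and 172 without replicate 3.

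In that comparison 7 lists fell and 0 rose, with few genes called in each. Fry called 1 list there and camera with an estimated correlation 0. Phagocytic receptor genes (1 of 25 higher and 5 lower, 2 and 10 adjusted over the list alone, median -0.60, adjusted p = 3.0e-10, adjusted p = 0.169 with an estimated correlation) fell. Border macrophage markers (0 of 5 higher and 2 lower, 0 and 3 adjusted over the list alone, median -0.88, adjusted p = 5.6e-05, adjusted p = 0.353 with an estimated correlation) fell, as did alternative activation genes (0 of 11 higher and 2 lower, 0 and 5 adjusted over the list alone, median -0.81, adjusted p = 0.000793, adjusted p = 0.684 with an estimated correlation). MHC class I genes (0 of 15 higher and 2 lower, 0 and 6 adjusted over the list alone, median -0.22, adjusted p = 0.00116, adjusted p = 0.684 with an estimated correlation) fell by the same test. Homeostatic microglia genes (0 of 16 higher and 2 lower, 1 and 5 adjusted over the list alone, median -0.38, adjusted p = 0.00935, adjusted p = 0.851 with an estimated correlation) fell as well. Interferon response genes (0 of 25 higher and 1 lower, 0 and 4 adjusted over the list alone, median -0.46, adjusted p = 0.00580, adjusted p = 0.996 with an estimated correlation) lost their call without Abcd1 KO replicate 3 (0.0827). Cholesterol synthesis genes (0 of 23 higher and 2 lower, 0 and 4 adjusted over the list alone, median -0.13, adjusted p = 0.00935, adjusted p = 0.996 with an estimated correlation) lost theirs without Abcd1 KO replicate 3 (0.0827) or DKO replicate 1 (0.0970). Antioxidant genes (adjusted p = 0.0589) were called with the replicate block (0.0156) and without Abcd1 KO replicate 2 (0.0308), and lysosome genes (0.0890) without Abcd1 KO replicate 3 (0.0295). On chromosome 8, where the median of all genes was -0.29 in this comparison, lie 5 of the 24 antioxidant and 4 of the 36 lysosome genes. Chil3 replicate 1 stood at 11.1 times the mean of the others in Abcd1 KO. Its fall in DKO (-5.57, SE 1.34, adjusted p = 0.0350) lost its call without Abcd1 KO replicate 1 (0.181) or 2 (0.0594) or DKO replicate 1 (0.0942), 2 (0.162) or 3 (0.174).

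DKO was compared with Abcd2 KO, and the interaction was tested, to ask whether the effect of one edit depends on the other. Spink5 was at least 694-fold and Il7r at least 241-fold higher in DKO than in Abcd2 KO. Mid2, a ubiquitin ligase, was higher by a ratio of 796 (interval 220 to 6576), and Chil3 (-11.33, SE 1.68, adjusted p = 0.00012) and Rnase2a (-10.46, SE 1.23) were lower. This contrast called 6112 genes (41.8%), 3169 higher and 2943 lower. Between Abcd1 KO and WT 7681 genes were called, and 2352 of them changed the same way here, 1195 the opposite way (r = 0.204 across genes). Abcd2 KO against WT called 8259 genes and DKO against Abcd1 KO 476, with 113 the same way, 215 opposite (r = -0.15). The interaction was called in 6498 genes (44.4%), 3132 above and 3366 below 0. For 3578 of them (55.1%) both single mutants and DKO differed from WT in the same direction and the interaction was opposite to it. The interaction of Abcd1 itself was -0.83 (adjusted p = 0.000412).

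Whole chromosomes were shifted in several contrasts. On chromosome 8 the median was -0.29 in DKO against Abcd1 KO, with 94.5% of 561 genes at 5 CPM or more lower (camera adjusted p = 1.8e-28, adjusted p = 2.3e-07 with an estimated correlation). On chromosome 1 it was -0.15, with 87.4% of 588 lower (7.0e-09, 0.0138 with an estimated correlation). These chromosomes held 113 and 39 of the 307 genes lower in that contrast. Abcd2 KO lay below Acox1 KO on chromosome 14 (median -0.25, adjusted p = 2.1e-13, adjusted p = 0.00035 with an estimated correlation). The median was -0.01 over 101 genes between 7.82 and 34.7 Mb (Flnb to Wapl) and -0.40 over 246 genes between 36.9 and 123 Mb (Ccser2 to Tmtc4), a division made after seeing the data. That contrast called 605 genes, 110 of its 222 lower ones on chromosome 14. The contrast was added after the data were seen. Its count was 1505 with the replicate block, 1021 with DESeq2, 282 on its own libraries, 297 on replicates 2 and 3, 318 without Acox1 KO replicate 2 and 353 without Acox1 KO replicate 3. Between the pairs, Abcd1 KO and DKO against Abcd2 KO and Acox1 KO, medians were -0.42 to -0.34 on chromosome 17, -0.31 to -0.29 on chromosome 6, and -0.25 to -0.22 on chromosome 2. They were -0.26 to -0.21 on chromosome 12 and 0.20 to 0.21 on chromosome 13, and within pairs these chromosomes differed by at most 0.045. In all 12 mutant libraries the median lay at least 0.1 to one side of WT on 3 chromosomes, a cutoff set after seeing the data, with genotype medians on chromosome 3 (0.27 to 0.37), chromosome 9 (-0.29 to -0.16) and chromosome 10 (0.10 to 0.18). On chromosome 3 the adjusted p was 0.000484 in Abcd1 KO, 0.0668 in Abcd2 KO, 0.000341 in DKO and 0.0443 in Acox1 KO. With an estimated correlation the adjusted p was 0.0237, 0.131, 0.0158 and 0.159. Chromosome 9 was called only in Acox1 KO (adjusted p = 0.0443, adjusted p = 0.0990 with an estimated correlation), and chromosome 10 in none (adjusted p = 0.144 to 0.452). Chromosomes 5, 7, 13, 15 and M also lay to one side in all 12, by less than 0.1 in some libraries. Of these chromosome 13 (0.11 to 0.32) was called in Abcd1 KO (adjusted p = 0.00481, adjusted p = 0.0482 with an estimated correlation) and DKO (adjusted p = 0.00289, adjusted p = 0.0346 with an estimated correlation).

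**Figure D4:**
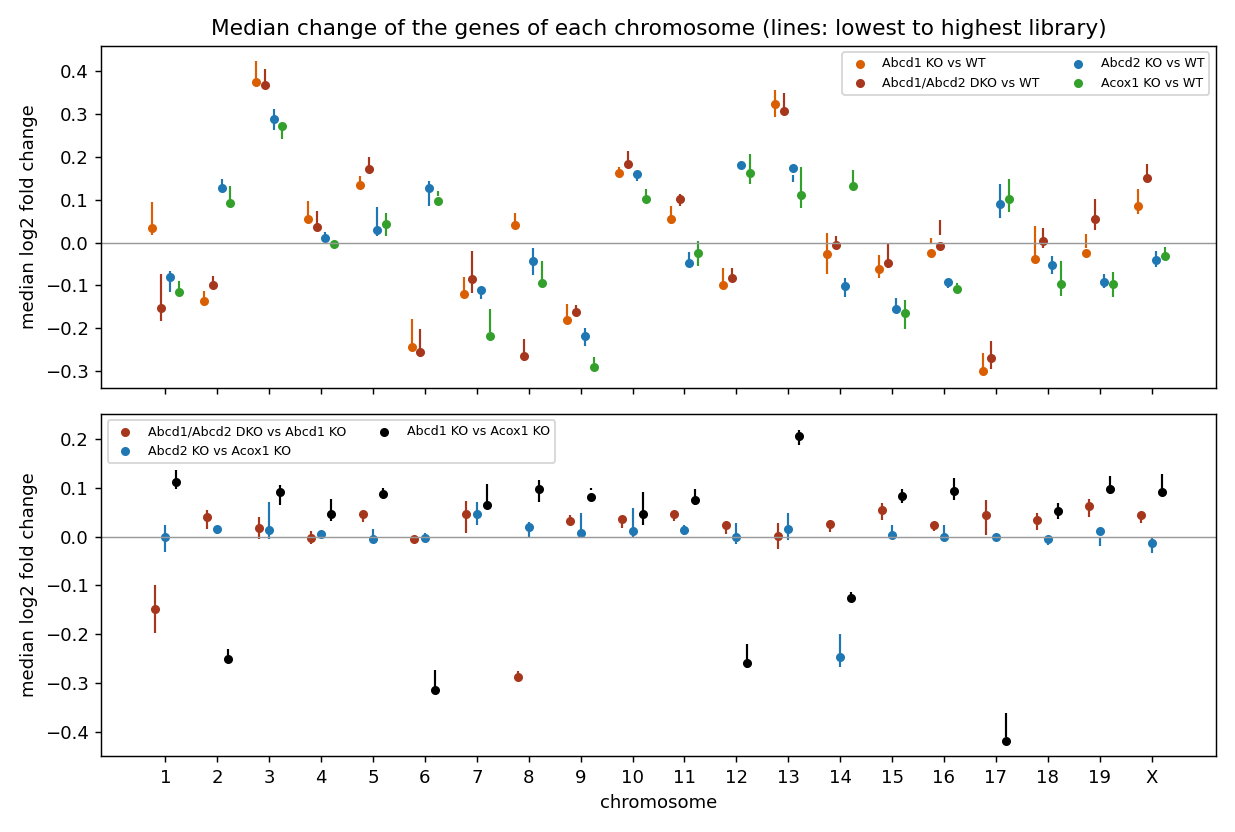
Median log2 fold change of the genes of each chromosome, with points from the fitted values and lines from the lowest to the highest library median, for the 4 mutants against WT (upper panel) and for DKO against Abcd1 KO, Abcd2 KO against Acox1 KO and Abcd1 KO against Acox1 KO (lower panel). Chromosome 8 lies at -0.29 in DKO against Abcd1 KO and chromosome 14 at -0.25 in Abcd2 KO against Acox1 KO.

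A set of genes expressed in WT was silent in the mutants, a count added after the data were seen. Of 9965 genes with at least 5 CPM in WT, 57 in Abcd1 KO, 75 in Abcd2 KO, 57 in DKO and 88 in Acox1 KO had at most 3 counts over the group. Of the 105 that were silent in any mutant 37 were silent in all 4, where independent sets would share 2.2e-05, and these lay on 17 chromosomes. They include Qsox1, Rnd3, Plac8, Sdr39u1, Casd1, which adds O-acetyl groups to sialic acids, Lamtor4 and Cd69, an early activation antigen of lymphocytes. In the reverse direction 0 genes were silent in WT and at 5 CPM or more in all 4 mutants, and 3 in any.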

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

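The tests of a history shared by the mutant lines and of copy number shared within a pair of lines, and of genes with unshifted neighbours, were chosen only after the result was seen, as were the counts of silent genes and the contrast of Abcd2 KO with Acox1 KO.

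The interaction of the Abcd1 and Abcd2 edits differed from 0 in 6498 genes, so that the difference between Abcd2 KO and WT was not the one between DKO and Abcd1 KO. The genes with the largest positive values were Spink5 (15.85, SE 1.21, total counts of 56 in WT, 7 in Abcd1 KO, 0 in Abcd2 KO and 2568 in DKO), Endod1 (14.63), Rnd3 (14.49), Itih5 (13.93) and Hdac9 (13.87). For Endod1 the total counts were 4430 in WT, 1 in each of Abcd1 KO and Abcd2 KO and 11 in DKO. Hdac9, a histone deacetylase, had 3876, 41, 3 and 541. Rnd3 had 2374 counts in WT and 0, 0 and 1 in the mutants, and its call was lost without DKO replicate 2 (adjusted p = 1). The largest negative values belonged to Chil3 (-11.87, SE 1.91), Chil4 (-10.41), the ribonuclease Rnase2a (-9.57), Iqsec3 (-9.07), a regulator of ARF GTPases, and Asap2 (-9), which acts on the same family. Chil3 had 23436 counts in WT, 44022 in Abcd1 KO, 1715252 in Abcd2 KO and 838 in DKO. In Acox1 KO, where neither transporter gene was edited, the counts were 0 for Spink5, 9 for Endod1, 0 for Rnd3, 0 for Itih5, 1 for Hdac9, 833463 for Chil3 and 965 for Chil4. Chil4 lost its call without Abcd1 KO replicate 1 (adjusted p = 0.0592). Fitted values of genes with 0 to 3 counts in a group depend on the prior count and are no bounds. Of 100 regroupings of the 12 libraries 1, the real one, gave as many genes, and the highest other gave 4283. Regroupings mix libraries of different lines, so they ask whether the genotypes differ at all and not whether an interaction is present. With no separate clones named, they cannot exclude chance differences between lines. In 3578 of the 6498 genes both single mutants and DKO differed from WT in the same direction and the interaction was opposite to it, so a difference from WT that all mutants share may account for these, and a dependence of one edit on the other stays open.

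A change shared by all 4 mutants covered 4063 genes. In simulations of unchanged mutants against 1 redrawn WT group 0 were shared, but unchanged mutants give almost no calls, so that 0 says little. Covariances of fold changes were 1.95 to 2.68 over the pairs of mutants, against 0.0367 to 0.0375 simulated. This argues against a spread between WT libraries of the simulated size as the sole source. A WT culture that differs as a whole from the edited cells was not simulated. Of 100 regroupings of the 15 libraries 1, the real one, gave as many genes, and the highest other gave 0. Regroupings mix libraries of different lines, so they show only that the libraries of a line resemble each other. They cannot tell whether the lines differ by chance. The mean correlation of fold changes was 0.809 after the median of the 50 nearest genes was subtracted and 0.805 before. Simulated unchanged mutants gave 0.505. This argues against copy number of segments long enough to move that median, acting on their own genes, as the whole cause. Effects of such segments on genes elsewhere stay in the correlation and were not tested. Single genes and shorter segments were not tested as a source of the shared change. A history shared by the mutant lines and not by the WT cells, such as descent from another passage or from a selected clone, may account for it, since the medians of 3 chromosomes (3, 9 and 10) lay at least 0.1 to the same side of WT in all 12 mutant libraries. Chromosome 10 was called in no mutant, and chromosomes 5, 7, 13, 15 and M lay to one side in all 12 by less than that in some. That history and an effect common to the 3 edited genes stay open, because the labels name no separate clones within a genotype.

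The mutants fell into the pairs Abcd1 KO with DKO and Abcd2 KO with Acox1 KO, although Acox1 KO shares no edited gene with Abcd2 KO and DKO shares one with Abcd2 KO as well. The pairs appeared in 3 of 3 replicate numbers, which argues against a culture batch confined to 1 number as their source. Each number holds all 5 genotypes, so lines grown or handled together in pairs in every batch were not tested. Copy number shared within a pair may contribute, because 5 autosomes differed by at least 0.15 in all comparisons across pairs and by less than 0.1 within both. Long segments of altered copy number, acting only on the genes within them, are argued against as the whole cause by 1362 genes. Their 50 nearest genes differed across the pairs by a median of at most 0.1. Among the 1362 genes, comparisons across the pairs that share no library correlated at 0.764 on average, and at 0.647, 0.764 and 0.798 in the replicates. Over all genes of at least 5 CPM the lowest distance across pairs was 1.57 times the highest within pairs after the subtraction of neighbours, and the replicates gave 1.18, 1.67 and 1.86. Copy number of single genes, and of segments too short to move the median of the 50 nearest genes, stays open. So do effects of long segments on genes outside them, which would also reach the 1362 genes. Clonal origin and genotype are confounded, and an effect of the edited genes stays open as an untested explanation.

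The 3 against 3 comparisons allow 10 splits of the libraries, so that the share is never under 0.1, and in each 1 split, the real one, gave as many genes. The real counts were 7681 (Abcd1 KO), 8259 (Abcd2 KO), 7598 (DKO) and 7330 (Acox1 KO) against WT, with highest other counts of 0, 5, 0 and 0. For DKO against Acox1 KO (5084), Abcd1 KO (476) and Abcd2 KO (6112), and for Abcd2 KO against Acox1 KO (605), the highest other count was 0.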

How the results depend on the processing

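The fit on replicates 2 and 3 was chosen only after the result was seen. Among 776 values of named genes 13175 alternatives were run: 12678 left the value on its side of the threshold, 489 ended a call, 8 gave one and 0 reversed a direction. For 192 list values and 2304 alternatives these numbers were 2144, 78, 82 and 0. Of the 82 gained calls 58 came from fry, which does not compare a list with other genes. Of the 78 lost 41 came from the estimated correlation and 7 from fry. With at least 2-fold or with glmTreat against a 1.5-fold change, counts fell to 3281 and 3262 (Abcd1 KO), 3452 and 3532 (Abcd2 KO), 3281 and 3278 (DKO) and 3023 and 2996 (Acox1 KO) against WT, 1462 and 1458 in all 4 mutants, 1889 and 1634 (DKO against Acox1 KO), 2146 and 1824 (DKO against Abcd2 KO), 3336 and 2874 (interaction), 203 and 86 (DKO against Abcd1 KO) and 276 and 132 (Abcd2 KO against Acox1 KO). An adjusted p under 0.01 left 3313 (DKO against Acox1 KO), 4002 (DKO against Abcd2 KO), 4301 (interaction), 179 (DKO against Abcd1 KO) and 259 (Abcd2 KO against Acox1 KO). These drops follow from the stricter thresholds. DKO against Abcd1 KO gave 868 genes with DESeq2, 1106 on its own libraries, 1250 with the replicate block, 273 on replicates 2 and 3 and 172 to 393 with 1 library left out. Abcd2 KO against Acox1 KO gave 1021, 282, 1505, 297 and 318 to 543 in the same order. Correlations between mutants over genes of at least 5 CPM were 0.798 (Abcd1 KO with Abcd2 KO), 0.801 (Abcd1 KO with Acox1 KO) and 0.728 (DKO with Acox1 KO), and with 1 library left out 0.766 to 0.786 for the first and 0.706 to 0.724 for the last. The cause was not tested, except that fits without libraries have fewer samples. The replicate block gave 9641 genes for Abcd2 KO against WT, where not every number paired the libraries, with Abcd2 (adjusted p = 0.0175) and inflammatory cytokine genes (0.0430) called, and changed no call of a list or named gene beyond these and those given beside their results. Total-count scaling moved the median of all genes by -0.12 in Abcd2 KO against WT and by 0.14 in the interaction, where the higher share of calls went from 48.2% to 58.9%. That share went from 50.7% to 41.1% in Abcd2 KO and from 49.7% to 42.8% in Acox1 KO against WT, and from 51.8% to 61.6% in DKO against Abcd2 KO. Depth limits genes at or under 3 counts per group.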

Other observations

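The tests of silent genes and of their neighbours were run on a count chosen only after the result was seen.

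Some genes outside the called lists differed in the same direction in all 4 mutants. Mbp, myelin basic protein, which BV-2 cells expressed at 46.4 ± 6.45 CPM in WT, fell by 3.79, 4.43, 3.34 and 4.90 in Abcd1 KO, Abcd2 KO, DKO and Acox1 KO. Hspa8, a constitutive chaperone, rose by 1.01 to 1.24, and Gsr, glutathione reductase, fell by 1.18, 1.24, 1.31 and 0.87. Aldh1l1, a folate enzyme used as an astrocyte marker, rose from 2.28 ± 1.09 CPM, by 1.75 in Abcd2 KO and 2.15 in Acox1 KO. The fractalkine receptor Cx3cr1, typical of resting microglia, fell from 8.78 ± 3.67 CPM to 0.574 ± 0.456 in Abcd1 KO and 0.921 ± 0.0592 in DKO. It was lower by ratios of 381 (interval 105 to 3148) in Abcd2 KO and 324 (110 to 1572) in Acox1 KO.

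Replicate 1 had the highest Chil3 in all 5 genotypes, at 2.33 (WT), 11.1 (Abcd1 KO), 3.57 (Abcd2 KO), 2.28 (DKO) and 3.26 (Acox1 KO) times the mean of the others. Arg1 was highest in replicate 1 in all genotypes except WT, where replicate 3 (1163 CPM) exceeded replicate 1 (1101 CPM), and WT replicate 2 had 39.7 CPM.

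The 37 genes silent in all 4 mutants might reflect deletions spanning neighbours, or silencing in a common ancestor of the lines. Of these genes 67.6% (25 of 37) had both tested neighbours above 3 counts over the group in every mutant. That bar is low, since Scd1, with 27781 counts in WT, passes it at 5 to 28 counts in the mutants. Genes removed by the low-count filter were not considered as neighbours. Adjacent pairs among the 37 numbered 0, where random draws gave 0.0879 on average. The counts show only that the tested neighbours of the 25 kept some reads, so deletions of more than 1 gene stay open. Deletions within a single gene cannot be seen in gene-level counts.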
